A study of Mus musculus with 22 samples.

How the data were processed

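The series holds RNA sequencing of bone marrow-derived macrophages from Il10-deficient C57BL/6 mice aged 6 to 12 weeks, left untreated or given lipopolysaccharide (LPS, a Toll-like receptor 4 ligand), recombinant interleukin-10 (IL-10) or both, each at 100 ng per ml. The 22 libraries form 2 separate tables, one for 3 h of treatment (8 libraries, 4 groups) and one for 6 h and 12 h (14 libraries, 7 groups that share 1 control group), with 2 libraries per group. The labels do not give the time at which the control of the second table was taken, the deleted allele, or whether replicates came from separate cultures or animals. The p-value of a gene-wise test therefore measures the spread between these libraries, pooled over all groups of a table, and no p-value here is known to hold beyond these libraries.

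Per the labels, RNA was purified on columns with a DNase step and made into libraries with a TruSeq kit, whose strand setting is not given. The submitters' processing notes name TopHat2, DESeq2 and the GRCm38 genome, without versions. The counting tool and the gene annotation are not given in the sources used here. The deposited values are a signal per gene, namely read counts that the authors divided by a size factor per library, in 2 tables with 38293 genes each. Every column proved to be a whole number of reads times a constant, within 0.01 reads for 100.0% of values, so the reads behind each value were recovered. The recovered depth ran from 9337222 reads in the first 3 h control to 31772075 in the first library of LPS with IL-10 at 6 h, and a single read was worth 0.588 to 2.17 normalized reads. The deposited factors were 0.949 to 0.971 times the median-of-ratios factors recomputed from the recovered reads in the 3 h table, a nearly constant ratio, and 1.0 times in the other. Both tables were normalized separately, and levels were never tested across them.

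Genes were named by the symbol of the second table, or by that of the 3 h table where the second had none. Where neither had one, GENCODE M21 (GRCm38) gave it through the gene identifier. GENCODE M21 holds 36345 of the identifiers and also gave the coordinates. For 3 h, 27 symbols had been turned into dates, and these were not used. For 2008 genes the tables give different symbols for the same identifier, so genes were joined by identifier. Genes in families with near-identical members, such as Saa, Gbp, Ifit, Serpina3, histocompatibility and Ccl genes, and genes that overlap another on either strand can share reads, because neither the counting nor its use of strand is stated.

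The test of every gene-wise comparison was limma 3.58.1 (eBayes with trend, R 4.3.3), on log2 of the normalized value plus 1, fitted to all groups of a table together, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes entered with at least 10 normalized reads in at least 2 libraries (12338 genes at 3 h, 12817 at 6 h and 12 h). All tests are two-sided. Changes are on the log2(value + 1) scale, which understates changes of weakly expressed genes. They are given as log2 change ± SE, and levels as mean ± SD of normalized reads (n = 2 libraries per group). The SE is pooled over all groups of a table, so an SE at 6 h also carries the spread between the 12 h libraries. Where one group had 0 reads, the fold is a lower bound against 3 reads over that group. With 1 to 3 reads it is a ratio with an exact 95% interval. These intervals and bounds cover counting error only. The comparisons were LPS against control, IL-10 alone against control, LPS with IL-10 against LPS (called IL-10 during LPS), the interaction (whether the IL-10 effect depended on LPS) at each time, and, within the second table, the differences between 12 h and 6 h.

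The design, the alternatives, the genes to name and 30 gene lists from textbook knowledge were fixed before the data were examined. The genes to name were the 8 largest rises and 8 largest falls for IL-10 during LPS, 5 and 5 elsewhere, among genes past the threshold whose replicates did not overlap and that reached a mean of 100 normalized reads, together with a fixed panel of 29 cytokine, receptor and metabolic genes and up to 4 genes of each list with the smallest p. The overlap of replicates was not checked for the interactions or for the difference between times in the IL-10 effect during LPS. The genes shown by single libraries, such as Mki67 and Rsad2, were chosen after their values were seen. Results for some genes are not reported here. The lists cover proinflammatory cytokines, chemokines, interferon-stimulated genes, STAT3 and IL-10 response genes, negative regulators of Toll-like receptor signalling, immediate early transcription factors, MHC class I, MHC class II with co-stimulation, nitric oxide and prostanoid synthesis, inflammasome and pyroptosis, glycolysis, the respiratory chain, the tricarboxylic acid cycle, cholesterol synthesis, LXR targets, phagocytic and scavenger receptors, lysosome, alternative activation, matrix proteases, the unfolded protein response, cell cycle, NRF2 targets and macrophage identity. A further 7 lists hold markers of neutrophils, dendritic cells, B cells, T and NK cells, stromal cells, erythroid cells, and mast cells or basophils. Lists with at least 3 measured genes (25 at 3 h, 26 later) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry, which asks whether a set moves one way on balance without comparing it with other genes. List members were counted over all genes tested and adjusted over the list alone.

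Genes that LPS moved by at least 1 log2 unit in one table were taken as lists into the other, and overlaps of called genes were tested with Fisher's exact test, in 7 pairs of comparisons that share no library. The alternatives were pseudocounts of 0.5 and 5, no filter or a minimum of 50, quantile normalization, TMM factors, a fit of only the groups compared, the replicate number as a block, a minimum change of 1 log2 unit, limma without trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Scaling to equal library totals, library weights, removal of each library's trend on transcript GC content, and leaving out the first libraries of the 12 h groups together were added after the values were seen. In data simulated from these libraries, limma recovered 92% of 2-fold and 100% of 4-fold changes for IL-10 during LPS at 3 h, 26% and 91% at 6 h, and 23% and 93% at 12 h. Of its calls there, 7.7%, 12.7% and 9.4% were false, against 6.4%, 7.9% and 8% with edgeR and 8.4%, 14.7% and 21.5% with DESeq2. The 100 genes changed at each fold were picked from those with a mean of at least 50 normalized reads with LPS. Recovery of weaker genes was not measured. Each gene was drawn independently, with a dispersion estimated by edgeR. Replicate differences shared across genes are therefore not in the simulated data, and the rates may not hold for the real libraries. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.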

Results

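Bone marrow-derived macrophages that lack Il10 were sequenced after 3 h, 6 h or 12 h with LPS, with added IL-10, with both or untreated, so that the response to IL-10 from outside could be measured. There are 11 groups of 2 libraries in 2 separately normalized tables, 1 for 3 h and 1 for 6 h and 12 h, and each table has its own untreated group. The harvest time of the untreated group of the second table is not given. Changes against it at 6 h and 12 h, and the interactions there, may therefore include effects of time in culture. The depth was 9337222 and 21141137 reads in the 3 h controls, 18523109 and 20498533 with LPS, 20733520 and 21455291 with IL-10, and 19482003 and 17710215 with both. In the second table the controls held 15622553 and 26429009 reads. At 6 h there were 15162195 and 21738954 with LPS, 31772075 and 25082392 with LPS and IL-10, and 18284925 and 25021931 with IL-10. At 12 h there were 18909708 and 20929842 with LPS, 26448928 and 18412505 with both, and 23866227 and 22452452 with IL-10. In the second table the difference between replicates ran along transcript GC content, with rank correlations over 12688 genes of -0.81 in the control, -0.55, -0.70 and 0.49 for LPS, both and IL-10 at 6 h, and -0.21, 0.42 and 0.57 at 12 h. These correlations were not measured in the 3 h table.

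Il10 itself (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974, GRCm38) is the deleted gene, yet every library held reads from it. There is no wild-type group and the allele is not given, so these reads check little about the knockout. Il10 stood at 119 ± 33.9 normalized reads in the 3 h control, 509 ± 34.6 with LPS, 327 ± 17.8 with IL-10 and 1532 ± 61.6 with both. It rose with LPS (2.11 ± 0.17, adjusted p = 7e-06), with IL-10 alone (1.47 ± 0.17, 0.0033) and with IL-10 during LPS (1.59 ± 0.17, 4e-04), so reads from the locus rose with both signals at 3 h. In the second table it rose with LPS at 6 h (1.10 ± 0.35, but -0.03 at equal library totals), while its change with IL-10 during LPS was 0.95 ± 0.35 at 6 h and 0.56 ± 0.35 at 12 h (adjusted p = 0.069 and 0.42). The receptor gene Il10ra rose with LPS at 3 h (2.51 ± 0.09) and fell with IL-10 during LPS at 6 h (-2.05 ± 0.26), and Il10rb, its shared partner chain, had a change of -0.04 ± 0.08 with LPS at 3 h.

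LPS at 3 h switched on inflammatory cytokines, interferon and their enzymes. The interleukin-12 subunit Il12b rose by 11.59 ± 0.42 log2 units to 20806 ± 828 normalized reads, Il6 by 11.46 ± 0.21, the vasoconstrictor precursor Edn1 by 10.22 ± 0.25, Il27 by 9.05 ± 0.16 and Il1b by 8.40 ± 0.10. Tnf went from 1945 ± 172 to 100662 ± 2927 normalized reads (5.70 ± 0.10). Interferon beta, Ifnb1, had 3 reads in the control and 14469 with LPS, a ratio of 5720-fold (95% interval 1960 to 27700). Il12a and Il23a had 0 control reads and rose at least 11.9-fold and 34.8-fold. The enzymes Nos2 (8.95 ± 0.29), Ptgs2 (7.52 ± 0.17) and Irg1 (5.43 ± 0.09, now named Acod1, which makes itaconate) rose, as did the feedback inhibitor Socs3 (6.79 ± 0.10). The largest falls were in Ccsap (-5.34 ± 0.30), the receptor Cd300lb (-5.08 ± 0.10), Bbs12 (-4.90 ± 0.32), Irf2bp2 (-4.83 ± 0.19) and Fam78a (-4.59 ± 0.42). The macrophage regulator Cebpa (-3.16 ± 0.17) and the growth regulator Myc (-3.94 ± 0.18) fell too.

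Of 12338 genes tested, 3400 were higher and 3201 lower with LPS at 3 h. The share of higher genes, 51.5%, fell to 39.6% with quantile normalization (2568 higher, 3912 lower, with the median gene moved by -0.12) and to 18.1% at equal library totals (1589 and 7179, median -0.56), because LPS libraries hold more normalized reads. All 18 measured proinflammatory cytokines and 18 of 19 chemokines rose (adjusted p = 0.028 with an estimated correlation for both lists), among them Cxcl10 (8.62 ± 0.09), Ccl5 (8.57 ± 0.10) and Ccl4 (6.81 ± 0.11). All 34 interferon-stimulated genes rose (0.068), led by Oasl1 (7.55 ± 0.12), Ifit1 (7.24 ± 0.14) and Cmpk2 (7.01 ± 0.11). Of the negative regulators 18 rose and 2 fell of 22 (0.028), with Dusp2 (6.0 ± 0.13) and Nfkbiz (5.34 ± 0.09). Of the MHC class II and co-stimulation list 11 of 14 rose (12 adjusted over the list alone, 0.049), such as Cd40 (5.58 ± 0.16) and Cd274 (5.47 ± 0.08). Of MHC class I genes 15 of 17 rose (0.15), and of STAT3 response genes 17 rose and 5 fell of 24 (0.095). Nitric oxide and prostanoid genes rose in 9 of 15 cases (0.068), but at equal library totals 5 rose and 3 fell and the median moved from 0.48 to -0.10. Of matrix proteases 11 rose and 3 fell of 17 (0.076), with Plau (-2.14 ± 0.08) down. Cell cycle genes went down, 21 of 30 with 1 rise (0.028), for example Cdc6 (-2.29 ± 0.14). Cholesterol synthesis went down too, 15 of 24 with 2 rises (17 over the list alone, 0.065), including Hmgcs1 (-1.10 ± 0.09).

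The smaller shifts of the other lists at 3 h of LPS depend on the scaling. Respiratory chain genes rose in 26 of 60 cases with none falling, glycolysis genes in 13 with 1 fall of 25 (2.48 ± 0.09 for Hk2), and phagocytic receptors in 14 with none falling of 25 (3.76 ± 0.12 for the Fc receptor Fcgr4). At equal library totals these turned to 0 up and 25 down, 2 up and 6 down, and 8 up and 13 down. The same switch of sign was met by the tricarboxylic acid cycle (6 rose and 2 fell of 23), lysosome (13 and 3 of 32) and the unfolded protein response (8 and 5 of 20). It was also met by LXR targets (3 and 3 of 15), NRF2 targets (7 and 2 of 19), immediate early factors (7 and 7 of 20) and the inflammasome (8 and 5 of 16). Macrophage identity switched as well (8 and 3 of 14, with a median of 0.35 and a mean of -0.22). Among alternative activation genes 5 of 9 rose, such as Irf4 (1.36 ± 0.31).

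Inflammatory cytokines were again among the genes that LPS raised steeply at 6 h and 12 h. Against the control of the second table Il12b rose by 13.52 ± 1.36 and 12.88 ± 1.36, Il6 by 13.23 ± 1.53 and 11.17 ± 1.53, and Il1a by 12.81 ± 1.52 and 11.39 ± 1.52. Nos2 rose by 12.01 ± 1.16 and 11.61 ± 1.16 and Ccl5 by 11.59 ± 0.81 and 11.80 ± 0.81. At 6 h the serine protease inhibitor Serpina3f (12.19 ± 1.29) and Edn1 (12.14 ± 1.50) rose as steeply, and Stat3 rose by 3.37 ± 0.22. At 6 h Ccsap had 0 reads and fell at least 123-fold, and the replication nuclease Exo1 fell 516-fold (95% interval 92.4 to 20400). Depdc1b fell 275-fold (95% interval 49.2 to 10900) and Arhgef39 119-fold (95% interval 40.7 to 579), while Fbxo5 changed by -7.21 ± 1.01. At 12 h the deepest falls were in the spindle gene Aspm (-5.08 ± 1.45), Exo1 (-4.63 ± 1.14), Sapcd2 (-4.52 ± 1.0), Depdc1b (-4.50 ± 1.11) and the uracil glycosylase Ung (-4.50 ± 1.25).

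Of 12817 genes, 3644 were higher and 4009 lower with LPS at 6 h, and 3036 higher and 3047 lower at 12 h. At equal library totals the shares of higher genes, 47.6% and 49.9%, became 16.7% (1641 and 8175, median -1.16) and 20% (1607 and 6415, median -0.75). Smaller shifts of the median came with edgeR (-0.26 and -0.15), TMM at 6 h (-0.12) and quantile normalization at 12 h (-0.13). Every proinflammatory cytokine of 20 rose at 6 h and 19 at 12 h (20 over the list alone), and 19 chemokines of 20 rose at each time. All 34 interferon-stimulated genes rose at both times, such as Isg20 (7.74 ± 0.42 and 7.57 ± 0.42) and Zbp1 (6.47 ± 0.32 and 5.94 ± 0.32). MHC class I genes rose in 16 and 14 of 17 cases, and MHC class II with co-stimulation in 11 of 15 at both times (1 fell at 12 h). STAT3 response genes rose in 18 and 20 of 25 with 2 falls each time, and negative regulators in 17 and 18 of 22 with 2 falls each time. Cell cycle genes fell in 27 and 30 of 30 cases, with Ccnd1 at -2.89 ± 0.32 and -2.14 ± 0.32. These directions held under every scaling, but with an estimated correlation none of the lists passed (adjusted p of at least 0.32 at 6 h and 0.22 at 12 h). The respiratory chain (21 and 8 of 60 up), lysosome (11 and 14 up of 32, 4 and 2 down) and the unfolded protein response (11 and 10 of 20 up, 2 down each time) changed direction at equal library totals. The first LPS library at 12 h stood nearer to the control, with Tnf at 38460 against 131400 and the proliferation marker Mki67 at 4159 against 874.1. Without the second LPS library 3794 genes changed at 12 h, and without the first library of each 12 h group 5239, with all 20 cytokines and 34 interferon-stimulated genes still up.

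**Figure D1:**
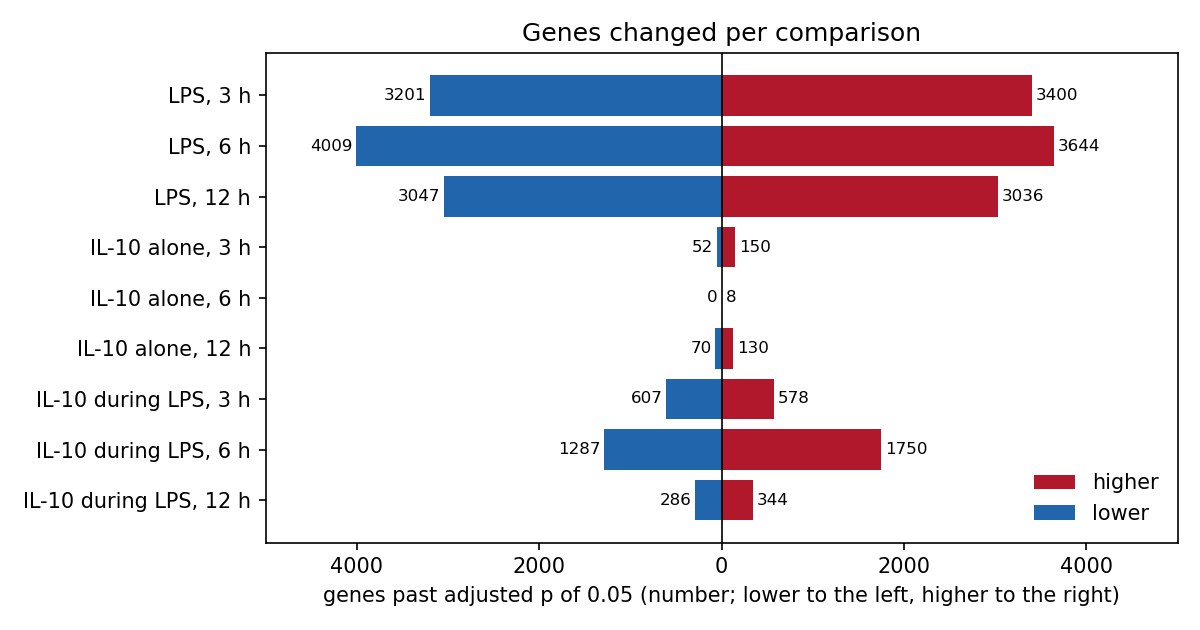
Number of genes past the threshold (horizontal axis, genes) for each comparison and time, with bars for genes higher and lower. IL-10 alone changed 202, 8 and 200 genes at 3 h, 6 h and 12 h, and LPS changed 6601, 7653 and 6083.

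With IL-10 alone at 3 h the largest rises were in Socs3, the STAT3-induced inhibitor of cytokine receptors (2.79 ± 0.10, adjusted p = 4.1e-06), the endothelin receptor Ednrb (2.56 ± 0.14), the interleukin-4 receptor chain Il4ra (2.38 ± 0.17), Nxpe5 (2.34 ± 0.14) and the glycosyltransferase Gcnt2 (2.27 ± 0.12). Stat3 (1.33 ± 0.08), Il1rn (0.77 ± 0.10), Nfil3 (0.88 ± 0.15), the scavenger receptor Mrc1 (0.97 ± 0.11) and the Fc receptors Fcgr2b (0.93 ± 0.08) and Fcgr3 (0.77 ± 0.08) rose as well. The largest falls were in the neutrophil chemokine Cxcl2 (-1.89 ± 0.10), Srgap3 (-1.18 ± 0.18), Tns1 (-1.16 ± 0.24), Plekhg1 (-1.05 ± 0.18) and Nol4l (-1.02 ± 0.12). The low resting Tnf (-0.96 ± 0.10), Myc (-0.95 ± 0.18) and Plau (-0.88 ± 0.08) fell too. In all 150 genes were higher and 52 lower (edgeR called 202, DESeq2 274). STAT3 response genes rose in 10 of 24 cases (14 up and 2 down over the list alone, adjusted p = 0.11 with an estimated correlation), while for cell cycle genes none passed and the list median was -0.20 (0.16). The count moved to 641 and 1915 without the first or second control, 86 and 87 without an LPS library, 45 and 73 without an IL-10 library and 78 without either library of both.

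At 6 h IL-10 alone passed the threshold in only 8 genes, all higher, with limma, against 10 with edgeR and 44 with DESeq2 and 428 at an unadjusted p below 0.05. They include Socs3 (3.65 ± 0.40), Il4ra (3.0 ± 0.36), the chemokine Ccl8 (2.95 ± 0.30), Ednrb (2.82 ± 0.28), the surface antigen Ly6a (1.54 ± 0.22), Kif3a (1.53 ± 0.19) and the macrophage survival factor Cd5l (1.23 ± 0.18). Cholesterol synthesis was the list that moved with an estimated correlation (adjusted p = 0.0097, median 0.49), although no member passed alone and 2 did over the list alone, and Lss and Fdps had changes of 0.84 ± 0.18 and 0.83 ± 0.20. Of the STAT3 response genes 2 of 25 rose (10 over the list alone, 0.077), and of the LXR targets 1 of 15 (0.16). The count was 5 without the first control, and 0 or 1 without the first or second IL-10 library.

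By 12 h IL-10 alone had raised Ccl8 by 5.81 ± 0.30, Socs3 by 5.14 ± 0.40, the NAD-consuming enzyme Cd38 by 4.73 ± 0.48, the fibrinogen-like Fgl2 by 4.29 ± 0.36 and Ednrb by 4.26 ± 0.28. Il4ra (3.84 ± 0.36), Stat3 (1.54 ± 0.22), Cd5l (2.44 ± 0.18), the desaturase Scd1 (2.0 ± 0.21) and Mrc1 (1.56 ± 0.27) rose too. The transcription factors Egr1 (-4.97 ± 0.77), Fos (-2.64 ± 0.39) and Myc (-1.74 ± 0.24) fell. Other large falls were in Adgre4 (-3.40 ± 0.51), Nptx1 (-3.20 ± 0.58) and the fusion receptor Dcstamp (-2.72 ± 0.52). This comparison cannot tell these rises and falls apart from changes with time in culture, because the harvest time of the control is not given. A total of 130 genes were higher and 70 lower (edgeR 245, DESeq2 563). The total of 200 depends on the fit, with 0 genes when only the groups compared were fitted, 53 with library weights, 387 with quantile normalization and 871 with GC trends removed. Genes of oxidative defence fell in 5 of 19 NRF2 targets (8 over the list alone, adjusted p = 0.026 with an estimated correlation), such as Txnrd1 (-1.26 ± 0.14) and Slc7a11 (-1.96 ± 0.34). Cholesterol synthesis rose in 2 of 24 (7 over the list alone, 0.026), Fdps (1.09 ± 0.20) and Lss (0.94 ± 0.18). STAT3 response genes rose in 8 of 25 (13 over the list alone, 0.076), and LXR targets in 2 of 15 (6 over the list alone, 0.076). Phagocytic receptors rose in 5 of 25 with 2 falls (5 and 6 over the list alone), and immediate early factors fell in 4 of 19 (0.18). Without the first library of each 12 h group the median of phagocytic receptors went from 0.01 to -0.08 and that of LXR targets from 0.47 to 0.48. The first IL-10 library held more inflammatory transcripts than the second, with Rsad2 at 10810 against 795.9 and Nos2 at 1750 against 44. Without it 31 genes passed, and without the first library of each 12 h group 32 did. Of these none were NRF2 targets (median -0.60), cholesterol genes (median 0.62) or immediate early factors (median -0.40) and 3 were STAT3 response genes. Leaving out either LPS or either IL-10 library of 6 h gave 125 or 124.

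Given with LPS for 3 h, IL-10 lowered 11 of 19 measured chemokines and 11 of 18 cytokines, with 3 cytokines raised, and it raised a separate set of genes. With an estimated correlation neither list passed. The largest falls were in the neutrophil attractants Cxcl1 (-4.47 ± 0.32), Cxcl2 (-3.71 ± 0.10) and Cxcl3 (-2.92 ± 0.13) and in Ifnb1 (-3.66 ± 0.28). They were followed by Il12b (-3.17 ± 0.42), the protease Plau (-3.04 ± 0.08), the membrane chemokine Cx3cl1 (-2.75 ± 0.19) and the channel Kcnj2 (-2.66 ± 0.17). Tnf fell to 23460.3 ± 679.9 normalized reads (-2.10 ± 0.10, adjusted p = 3.3e-06). Il6 (-1.68 ± 0.21), Il1b (-1.34 ± 0.10), Il23a (-2.27 ± 0.48), Csf1 (-1.33 ± 0.10), Ccl2 (-1.82 ± 0.09) and the inflammasome sensor Nlrp3 (-1.46 ± 0.10) fell. Il12a went from 30 reads to 2, 14.2-fold (95% interval 3.59 to 122). The largest rises were in the metalloreductase Steap4 (5.63 ± 0.58), P-selectin Selp (5.07 ± 0.35), the adenosine receptor Adora3 (5.05 ± 0.25) and the co-stimulatory receptor Tnfrsf9 (4.19 ± 0.32). Next came the protease inhibitor Timp1 (4.13 ± 0.23), Il4ra (4.02 ± 0.17), the acute-phase gene Saa3 (3.98 ± 0.09) and the mTOR inhibitor Ddit4 (3.97 ± 0.34). Nos2, an inflammatory enzyme, rose rather than fell (2.60 ± 0.29). Further rises were in the glycolytic activator Pfkfb3 (3.29 ± 0.08), Il1rn (1.97 ± 0.10), Bcl3 (1.40 ± 0.22), Dusp1 (2.04 ± 0.10) and the metallothionein Mt2 (3.36 ± 0.27).

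In this comparison 578 genes were higher and 607 lower (edgeR 1242, DESeq2 1150). Cytokines fell in 11 of 18 cases with 3 rises (12 falls over the list alone) and chemokines in 11 of 19. STAT3 response genes rose in 16 of 24 with 1 fall (17 and 2 over the list alone). With an estimated correlation each of these lists had an adjusted p of 0.051. Interferon-stimulated genes did not go down with Ifnb1, since 4 of 34 rose and none fell (9 and 1 over the list alone, 0.74), such as Usp18 (0.66 ± 0.12). Cxcl10 changed by -0.04 ± 0.09 and Ifit1 by 0.34 ± 0.14. No MHC class I gene of 17 passed, and of MHC class II with co-stimulation 1 of 14 rose and 2 fell, among them Cd80 (-0.84 ± 0.19). Negative regulators split into 5 rises and 2 falls of 22, immediate early factors into 3 and 4 of 20, and NRF2 targets into 4 and 3 of 19. Matrix proteases split into 2 and 3 of 17 and phagocytic receptors into 6 and 1 of 25. None of 60 respiratory chain, 23 tricarboxylic acid cycle and 32 lysosome genes passed. The count rose to 2432 and 2448 without the first or second control, and fell to 505 and 543 without an LPS library and 473 and 494 without a library of both.

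With IL-10 during 6 h of LPS cytokines made up most of the largest falls. The growth factor Csf2 (-8.61 ± 1.51) and the chemokine Ccl17 (-8.04 ± 1.82) fell most, followed by Cx3cl1 (-6.58 ± 1.53), Cxcl3 (-6.17 ± 1.46), Il6 (-6.01 ± 1.53), Il1a (-5.70 ± 1.52) and Il12b (-5.52 ± 1.36). Il12a fell 293-fold (95% interval 99.5 to 1420) and Il23a 50.4-fold (95% interval 8.28 to 2070). Tnf went from 258429 ± 419 to 11305 ± 1095 normalized reads (-4.52 ± 1.13, adjusted p = 0.017). Its replicates lay close at 6 h, and the SE of 1.13 is pooled with the 12 h groups, where they lay far apart. Il1b (-4.73 ± 1.41), Cxcl2 (-4.99 ± 1.08), Ifnb1 (-4.67 ± 0.78), Csf1 (-4.38 ± 0.69), Osm (-3.21 ± 0.42), Nlrp3 (-3.11 ± 0.79) and the signalling inhibitor Cish (-4.96 ± 0.55) fell. The co-stimulatory genes Cd40 (-2.17 ± 0.59), Cd86 (-1.27 ± 0.42) and Icosl (-3.61 ± 0.56) fell too. Rises were led by the haemoglobin scavenger Hp (5.74 ± 0.55), Selp (5.41 ± 0.51), Adora3 (5.32 ± 0.32), Lhfpl2 (5.18 ± 0.20), Tm4sf1 (5.15 ± 0.43), the mitochondrial arginase Arg2 (5.02 ± 0.41) and Steap4 (4.95 ± 1.10). Zfp618 rose 113-fold (95% interval 31.1 to 936) and the cytosolic arginase Arg1 21.9-fold (95% interval 5.89 to 184) from 3 reads or fewer with LPS. Il4ra (4.02 ± 0.36), Timp1 (2.88 ± 0.27), Pfkfb3 (4.68 ± 0.41), the lactate carrier Slc16a1 (3.61 ± 0.28) and Hk2 (1.20 ± 0.17) rose too. Nos2, up at 3 h, had a change of -0.12 ± 1.16 (adjusted p = 0.95).

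Counts at 6 h were 1750 higher and 1287 lower (edgeR 2734, DESeq2 3200), or 57.6% higher, against 83.7% at equal library totals (3233 and 628, median 0.32). Cytokines fell in 15 of 20 cases with 2 rises (17 falls over the list alone) and chemokines in 14 of 20 (15). MHC class II with co-stimulation fell in 9 of 15, for example H2-Ab1 (-1.67 ± 0.33), and MHC class I in 10 of 17 (12 over the list alone), for example H2-D1 (-1.16 ± 0.25). Interferon-stimulated genes fell in 9 of 34, such as Oasl1 (-2.06 ± 0.51). The falls of MHC class I and interferon-stimulated genes rest on the scaling. With quantile normalization and at equal library totals the first list fell in 1 and 3 cases with 1 rise each, and the second in 1 and 2. Immediate early factors fell in 9 of 19 with 2 rises and negative regulators in 7 of 22 with 3 rises. Phagocytic receptors fell in 7 of 25 with 2 rises, NRF2 targets in 5 of 19 with 2 rises and the respiratory chain in 7 of 60 (0 over the list alone, and 0 with 3 rises at equal library totals). STAT3 response genes rose in 10 of 25 with 2 falls. Cell cycle genes, which LPS lowered, rose in 13 of 30 (2.40 ± 0.41 for Ccnb1 and 1.81 ± 0.45 for Aurka). With an estimated correlation the adjusted p was 0.46 for cell cycle and 0.41 for the other lists here. LXR targets (3 rose and 4 fell of 15), cholesterol synthesis (5 and 1 of 24), glycolysis (4 and 4 of 25, with a median of -0.18 and a mean of 0.17), macrophage identity (3 and 4 of 14) and the inflammasome (2 and 3 of 16) were mixed. Equal library totals changed the sign of the medians of glycolysis, the inflammasome, the tricarboxylic acid cycle, lysosome and the unfolded protein response. The count was 985 and 1565 without the first or second LPS library and 866 without the second library of both.

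At 12 h IL-10 during LPS raised Hp most, by 5.95 ± 0.55, followed by Saa1 (5.27 ± 0.75), Arg1 (4.75 ± 0.69) and Selp (3.92 ± 0.51). Tm4sf1 rose by 3.86 ± 0.43, the chitinase-like Chil1 by 3.86 ± 0.71, Abi3 by 3.85 ± 0.63 and the receptor Sirpb1c by 3.76 ± 0.26. Timp1 (3.60 ± 0.27), Il21r (2.92 ± 0.26), Il4ra (2.86 ± 0.36), the lipid carriers Pltp (2.13 ± 0.35) and Abca1 (1.20 ± 0.23) and the protease Mmp19 (2.32 ± 0.25) rose too. Falls were led by the chemokine receptors Cxcr3 (-4.13 ± 0.50) and Ccr7 (-3.37 ± 0.53), the growth factor Hbegf (-3.59 ± 0.54), and Cish (-3.46 ± 0.55). Syt7 (-3.33 ± 0.53), Ppfia3 (-2.84 ± 0.54), the heat-shock gene Hspa1b (-2.64 ± 0.34) and Ccnf (-2.52 ± 0.32) fell too, as did Cxcl16 (-1.15 ± 0.29), Icosl (-2.44 ± 0.56) and Hk2 (-0.86 ± 0.17). The cytokines themselves did not pass, with Tnf at -2.07 ± 1.13 (adjusted p = 0.36), Il12b at -3.84 ± 1.36 (0.14), Il6 at -2.54 ± 1.53 (0.41) and Il1b at -2.91 ± 1.41 (0.29). The replicates of that group lie far apart, with Tnf at 87530 in the first and 3275 in the second, Il12b at 20890 and 346.9, and Il6 at 46550 and 507.9.

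Among 12817 genes 344 were higher and 286 lower (edgeR 619, DESeq2 1044), and 54.6% higher became 65.8% at equal library totals (279 and 145) and 64.8% with edgeR. The total of 630 was 52 when only the groups compared were fitted, 259 with library weights and 2001 with GC trends removed. Without the first library of each 12 h group, a set chosen after its cytokine and other levels were seen that leaves 1 library per group, with the spread taken from the other groups, 404 were higher and 580 lower. Without these libraries the interaction at 12 h had a cytokine median of -3.42, against -2.01 with them, and a chemokine median of -3.3, against -1.51. With all libraries cytokines fell with IL-10 during LPS in 0 of 20 cases (median -1.43) and chemokines in 1 of 20 (-1.17), each with an adjusted p of 0.55 with an estimated correlation. NRF2 targets fell in 7 of 19 (1 up and 9 down over the list alone, 0.11 by the same test), such as Gclc (-1.43 ± 0.23) and the autophagy adaptor Sqstm1 (-1.53 ± 0.22). They fell in 4 without the first libraries. LXR targets rose in 4 of 15 (7 over the list alone, 0.43; 3 without the first libraries) and STAT3 response genes in 5 of 25 (6 over the list alone, 0.43; 6 with 1 fall without the first libraries). Cholesterol synthesis rose in 1 of 24 (0.30), MHC class II with co-stimulation fell in 1 of 15 (3 up and 9 down over the list alone, 0.55), and no MHC class I or interferon-stimulated gene passed. Cell cycle genes had a median of -0.78 with 1 fall of 30 (0.55), which turned to 0.35 with 2 rises and 3 falls without the first libraries. Of the unfolded protein response 2 of 20 fell (0.43), led by Psat1 (-0.92 ± 0.19). Counts with single libraries left out were 991 and 86 for the first and second library of both, 342 and 343 for IL-10 at 6 h and 375 and 377 for IL-10 at 12 h.

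**Figure D2:**
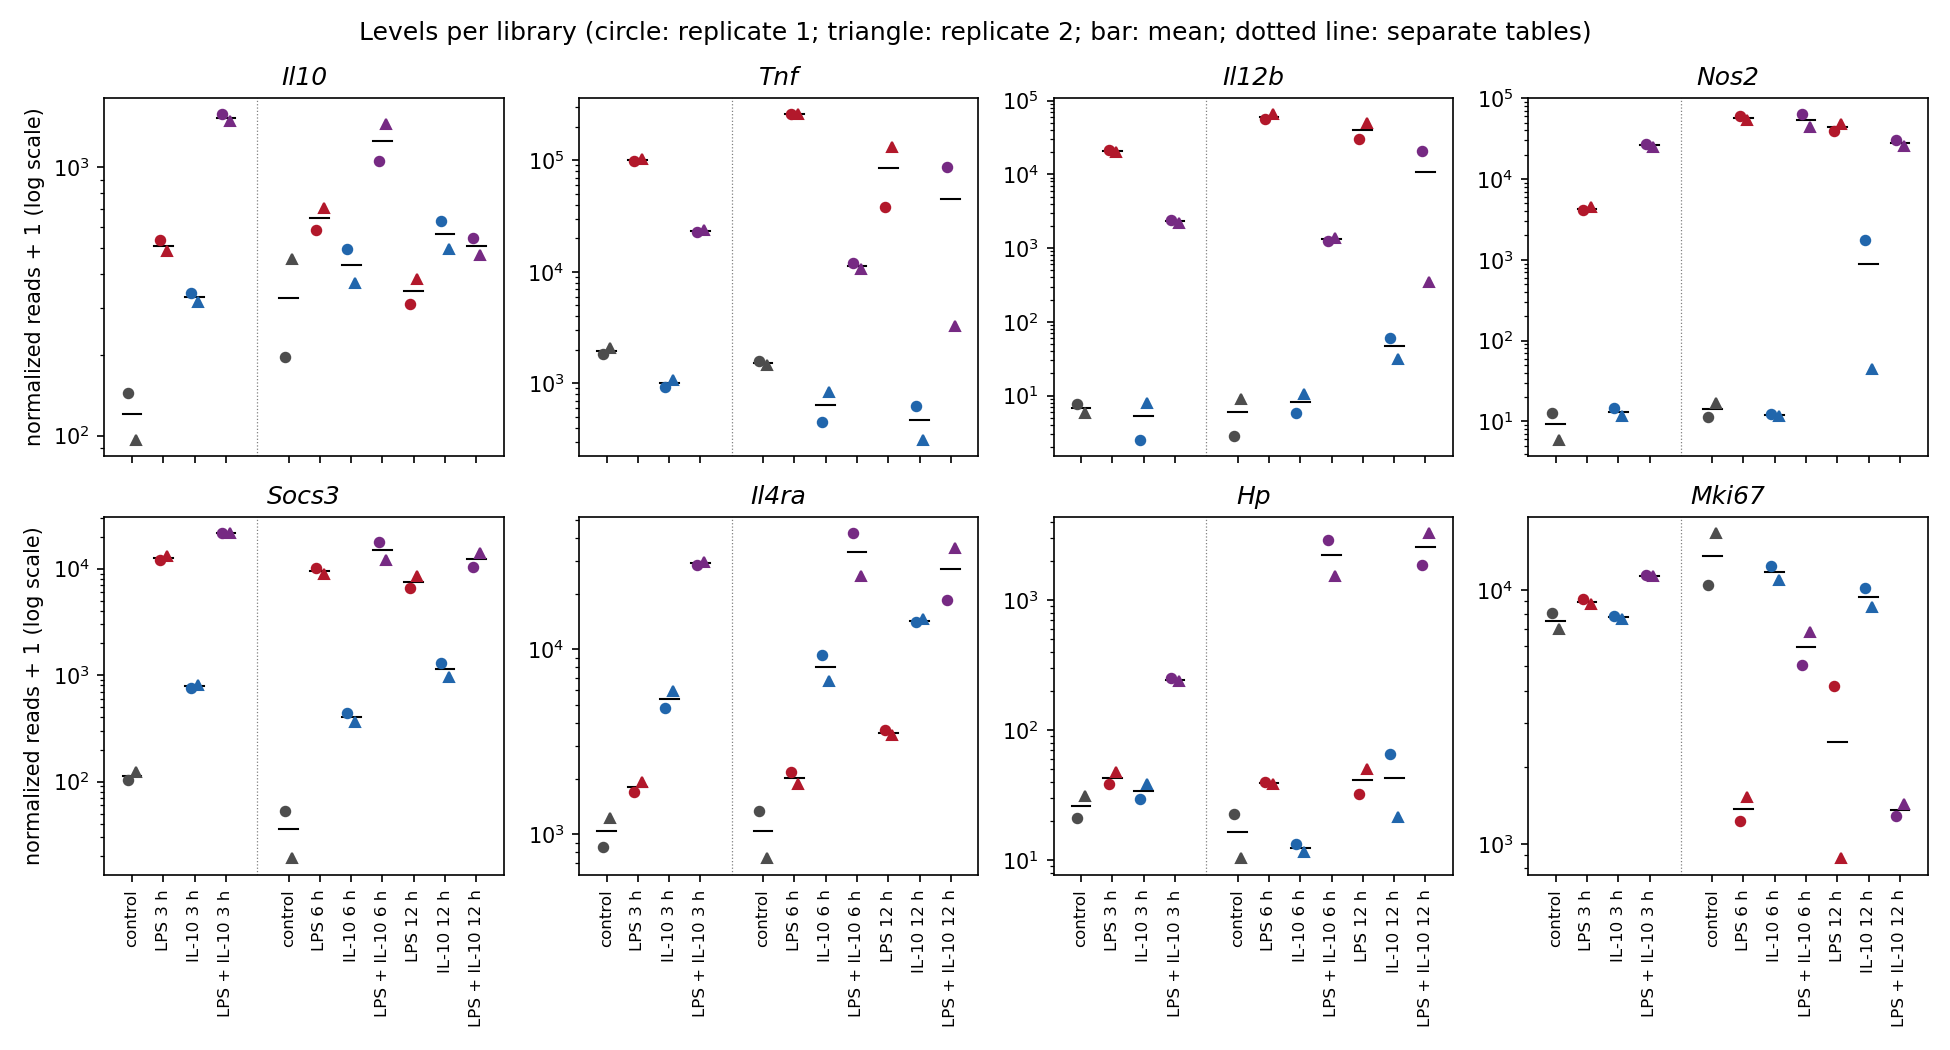
Normalized reads (vertical axis, log scale) of Il10, Tnf, Il12b, Nos2, Socs3, Il4ra, Hp and Mki67 in each group, with a circle for the first library, a triangle for the second and a bar for the mean. The first library of LPS with IL-10 at 12 h has Tnf at 87530 and the second at 3275.

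The interaction shows for which genes the IL-10 effect depended on LPS. At 3 h 181 genes had a higher and 163 a lower IL-10 effect with LPS (edgeR 360, DESeq2 410). Tnfrsf9 (4.85 ± 0.46), Steap4 (4.67 ± 0.82, from 0 control reads), Ddit4 (3.69 ± 0.48), Chil1 (3.43 ± 0.40) and Saa3 (3.42 ± 0.13) were raised by IL-10 more with LPS. On the other side were Ifnb1 (-4.08 ± 0.39, a value that rests on a control with 3 reads), Cxcl1 (-3.19 ± 0.45), Serpina3g (-3.01 ± 0.36), Serpina3f (-2.64 ± 0.56), Trib1 (-2.35 ± 0.23), Il1b (-1.91 ± 0.14) and Tnf (-1.14 ± 0.14). Socs3 also went this way (-2.0 ± 0.14). The count moved to 1227 and 1443 without a control, 120 and 140 without an LPS library, 164 and 210 without an IL-10 library and 103 and 113 without a library of both.

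At 6 h 571 genes had a higher and 290 a lower IL-10 effect with LPS (edgeR 877, DESeq2 1710). Above stood Hp (6.04 ± 0.78), the oxygen sensor Egln3 (5.61 ± 0.48), Saa1 (5.28 ± 1.06), Arg2 (5.21 ± 0.58) and Slc16a1 (4.16 ± 0.40). Below stood Cish (-5.29 ± 0.78), the interleukin-12 receptor chain Il12rb1 (-4.31 ± 0.62), Arhgap22 (-4.21 ± 0.57) and Csf1 (-4.13 ± 0.98). The share of higher effects, 66.3%, was 83.7% at equal library totals (937 and 183) and 55.1% with GC trends removed. Leaving out libraries gave 4220 and 328 (controls), 200 and 367 (LPS at 6 h), 151 (second of both at 6 h), 174 and 148 (IL-10 at 6 h), 1317 and 1326 (LPS at 12 h) and 430 and 433 (IL-10 at 12 h). At 12 h 19 were higher and 30 lower (1251 at an unadjusted p below 0.05, edgeR 66, DESeq2 257). Above were Hp (4.66 ± 0.78), the calgranulin S100a8 (3.53 ± 0.48), the kinase Fgr (3.33 ± 0.51), Fos (3.26 ± 0.55) and Sdc1 (3.16 ± 0.52). Below were Ccl8 (-5.77 ± 0.42), Fgl2 (-4.69 ± 0.51), Socs3 (-4.45 ± 0.57), the xenobiotic receptor Ahr (-3.75 ± 0.63) and Ntng2 (-3.51 ± 0.59). Ccl8 and Fgl2, raised by IL-10 alone, had changes of 0.04 ± 0.30 and -0.40 ± 0.36 with IL-10 during LPS, where LPS had raised them. The 38.8% above became 53.0% with edgeR. With 1 library left out the count was 26 (either LPS at 6 h), 24 (either IL-10 at 6 h), 89 and 88 (LPS at 12 h), 154 and 11 (both at 12 h) and 21 (first IL-10 at 12 h). A count of 106 passed without the first library of each 12 h group.

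Between 6 h and 12 h LPS itself moved 1422 genes up and 599 down. Higher were Jade1 (4.94 ± 0.33), the mTORC1-linked GTPase Rragd (4.92 ± 0.36), Lhfpl2 (4.83 ± 0.20), the receptor Cxcr4 (4.32 ± 0.29) and Kcnk13 (4.31 ± 0.31). Lower were Tnfsf4 (-3.08 ± 0.87), Lck (-2.44 ± 0.59), the hydroxylase Ch25h (-2.38 ± 0.73), Tra2a (-2.30 ± 0.65) and Cebpd (-2.12 ± 0.43). Hmox1 (2.91 ± 0.27), Trib3 (2.81 ± 0.36) and Slc40a1 (2.88 ± 0.27) rose, and Arg1 rose 9.03-fold (95% interval 2.26 to 78.5). The 70.4% higher became 92.7% at equal library totals (2451 and 192, median 0.38), 83% with edgeR, 49.3% with GC trends removed and 90.4% without the first 12 h libraries (208 and 22). Counts of 708, 713 and 495 genes passed without the first or second LPS library of 6 h or the first of 12 h.

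The IL-10 effect during LPS differed between the times in 34 genes upward and 114 downward (edgeR 142, DESeq2 732). This contrast subtracts the change of LPS alone between the times, so it shares libraries with that result and is not independent of it. A fall here can come from a rise with LPS alone, and Lhfpl2, the largest fall, was also among the largest rises of LPS alone. Above were Metrnl (2.41 ± 0.44), Inpp1 (2.07 ± 0.42), Plk2 (2.06 ± 0.32) and Rhob (1.89 ± 0.31). Below were Lhfpl2 (-4.49 ± 0.29), Ppp1r3b (-4.34 ± 0.33), Ccnf (-4.31 ± 0.46), Egln3 (-4.04 ± 0.48), Ankrd37 (-3.84 ± 0.35), Pfkfb3 (-3.14 ± 0.57) and Hk2 (-2.05 ± 0.24), which IL-10 raised at 6 h and lowered at 12 h. The 23% above became 33.7% with quantile normalization and 15.2% at equal library totals (20 and 112, median -0.23), and the count was 3 without the first 12 h libraries. It was 382 and 362 without a control, 22 and 56 (LPS at 6 h), 35 and 9 (both at 6 h), 61 and 62 (IL-10 at 6 h), 89 and 903 (LPS at 12 h), 24 (first of both at 12 h) and 63 (either IL-10 at 12 h). IL-10 alone differed between the times in 1 gene with limma and with edgeR, Ccl8 (2.86 ± 0.30), and in 72 with DESeq2 (589 at an unadjusted p below 0.05). The count was 60 without the second IL-10 library of 12 h and 0 without the first, without either LPS or IL-10 library of 6 h, or without either library of both at 6 h or 12 h.

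The IL-10 effects during LPS were shared between times more often than independent calls would give. The expected numbers and Fisher's test take genes as independent, and comparisons of the same table share an estimate of spread per gene. Genes with a small spread are called more readily in both, so overlaps can exceed the expected numbers for that reason too. Of 12095 genes in both tests 278 were higher at 3 h and 6 h (79.0 expected, Fisher p = 1.3e-94) and 236 lower (60.1, 9.9e-87), while 82 went opposite ways. For 3 h and 12 h 97 were higher in both (14.9) and 53 lower (13.2), and for 6 h and 12 h 226 (47.0) and 147 (28.7). IL-10 alone and IL-10 during LPS at 3 h shared 99 higher genes (7.0 expected) and 35 lower (2.6), and at 12 h 39 (3.5) and 17 (1.6). IL-10 alone at 3 h and 12 h shared 52 higher genes (1.5) and 3 lower (0.3), and LPS at 3 h and 6 h 2451 (938.3) and 2338 (1011.4). At 6 h IL-10 moved genes of both directions against LPS. Of 1552 genes that LPS induced at 3 h, 487 (31.4%) were lowered by IL-10 at 6 h against 7.1% of other genes, and 78 were raised. Of 1433 genes that LPS lowered, 571 (39.8%) were raised against 10.4% of others, and 38 were lowered. Camera gave p = 3.6e-16 and 4.0e-20 for these lists, and 0.15 and 0.11 with an estimated correlation. At 12 h 70 of the induced genes were lowered (4.5% against 1.9% of others) and 27 raised, and 55 of the lowered genes were raised and 19 lowered (p = 0.46 and 0.58 with an estimated correlation). At 3 h IL-10 moved the genes both ways. Of 2473 genes induced at 6 h it lowered 202 (8.2% against 4.1% of others) and raised 240 (9.7% against 3.4%). Of 2975 lowered genes it raised 120 (4% against 4.9%) and lowered 182 (6.1% against 4.5%). With an estimated correlation camera gave p = 0.38 for the induced list and 0.046, downward, for the lowered list.

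**Figure D3:**
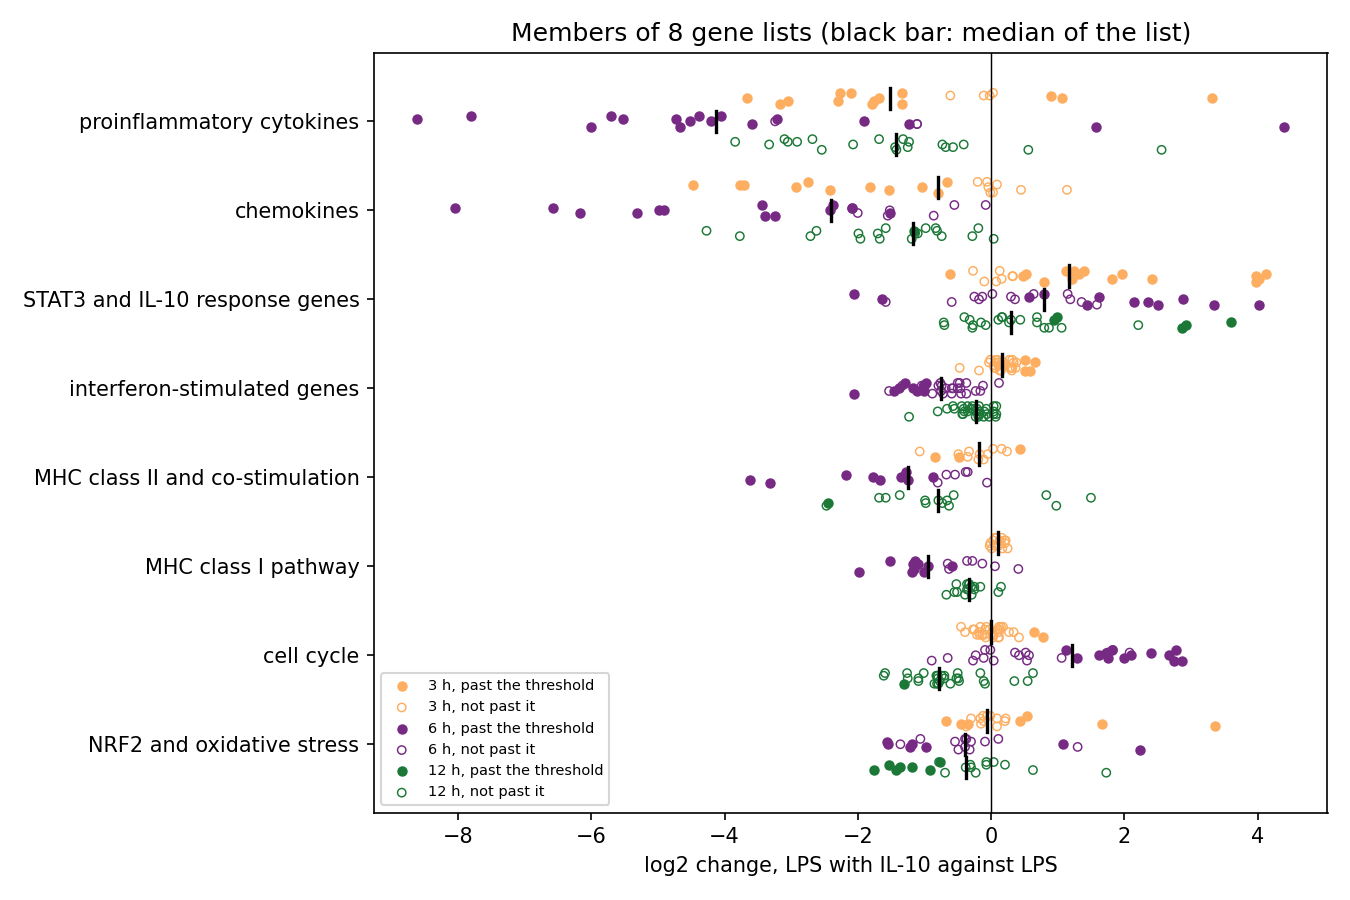
Change with IL-10 during LPS (horizontal axis, log2) of the members of 8 gene lists at 3 h, 6 h and 12 h, with filled points for genes past the threshold and a black bar for the median. The cytokine median was -1.51, -4.12 and -1.43.

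Markers of other cells were mostly missing or low. No erythroid marker, 1 T or NK marker (Klrb1c, -1.0 ± 0.47 with LPS at 3 h, not past the threshold), 2 B cell markers, 1 mast cell marker (Kit, 0.78 ± 0.55), 3 dendritic and 5 neutrophil markers were measured at 3 h. Of the neutrophil markers 4 rose with LPS at 3 h (median 1.17, and 2 rose at equal library totals). Dendritic markers measured at 6 h were 7, of which 3 rose with LPS, Xcr1 (5.41 ± 0.58), Clec9a (3.62 ± 0.66) and Dpp4 (1.67 ± 0.46). Of 3 stromal markers the matrix gene Dcn rose with LPS (5.35 ± 0.55) and Lum at least 52.4-fold from 0 reads. The neutrophil and macrophage gene S100a8 rose with IL-10 during LPS at 6 h (3.38 ± 0.34) and 12 h (2.92 ± 0.34), while S100a9, its partner, had changes of 0.36 ± 0.25 and 0.18 ± 0.25. B cell marker Cd79b fell with LPS at 6 h (-1.47 ± 0.32).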

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

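The tests of LPS-alone material in the first library of LPS with IL-10 at 12 h and of GC content as a part of the replicate differences were chosen after the values they measure were seen. So was the rule by which an explanation is argued against, that its needed bound is missed by more than the spread of the values.

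These results stand here because a test of the difference itself found that the IL-10 effect, or the LPS effect, was not the same in different groups or at different times. The IL-10 effect depended on LPS in 344 genes at 3 h, from Tnfrsf9 (4.85) to Ifnb1 (-4.08, with 3 reads in the control), in 861 genes at 6 h, from Hp (6.04) to Cish (-5.29), and in 49 genes at 12 h, from Hp (4.66) to Ccl8 (-5.77). It differed between 12 h and 6 h of LPS in 148 genes, from Metrnl (2.41) to Lhfpl2 (-4.49), in a contrast that is not independent of the change of LPS alone between these times. LPS alone differed between these times in 2021 genes, from Jade1 (4.94) to Tnfsf4 (-3.08), and IL-10 alone in 1 gene, Ccl8 (2.86). Every result at 12 h rests on groups in which the first library stood apart from the second.

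The first library of LPS with IL-10 at 12 h held more of some LPS-induced transcripts than the second, with Il1b at 127700 against 2135. The exchange of its label with that of the first LPS library needs a median weight of more than 0.5. Genes higher in the second library of LPS with IL-10 had a median of only 0.236 in the first LPS library (quartiles 0.118 to 0.39), which argues against it. The median did not fall below the bound set beforehand against an exchange, so by the rule first written the test cannot tell. A mixture with LPS-alone material is consistent with the values, because the second LPS library explained it with a weight of 0.543 over 117 genes higher in LPS and 0.55 over 302 genes higher with IL-10, a difference of 0.006. A weaker IL-10 response that scales all genes alike would give the same numbers and stays open. The design names no factor that parts the replicates, so no biological explanation was tested.

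The first LPS library at 12 h stood nearer to the control than the second, and cell cycle genes differed by a median of -1.77 log2 units (second minus first). Unstimulated cells or RNA in the library are consistent with the values, with control weights of 0.172 over 2079 genes higher in the control and 0.178 over 501 genes higher in LPS, a difference of 0.006, although the second set spreads from -0.019 to 0.339. A later or weaker response cannot be told apart from this. The bound of at most 0.05 set for it was wrong, since a response weaker in all genes alike, or a share of cells that did not respond, would also leave the 0.178 (quartiles 0.149 to 0.217) seen over 1795 genes lower in both 6 h LPS libraries and the second 12 h LPS library than in the control. No biological explanation was tested.

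In the second table the replicates of the control and of LPS with IL-10 at 6 h differed in the same genes, with a correlation of 0.70 between the differences. GC content as the whole cause missed the bound it needed. The correlation was still 0.42 once GC trends were removed, where less than 0.5 times the first value was needed. The trend was drawn on the median GC content of each gene's annotated transcripts and may leave a part behind, so this test cannot exclude GC content. As a part of the cause it is consistent with rank correlations of -0.81 in the control, -0.55 with LPS at 6 h and -0.70 with both. Transcript length (0.15 in the control, with more than 0.3 needed) and a different share of dividing cells (cell cycle median 0.17, upper quartile 0.49, with at least 0.5 needed) missed the bounds they needed. The bounds set beforehand against GC content, length and dividing cells were not met either, so by the rule first written these tests cannot tell. The labels give no batch, and no biological explanation was tested.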

How the results depend on the processing

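The settings of equal library totals, library weights, removed GC trends and the joint loss of the first 12 h libraries, and all settings of the overlaps and carried lists other than a pseudocount of 5, no filter, quantile normalization, the replicate block and a minimum change of 1 log2 unit, were chosen after the values were seen. Unless a sentence says why, the cause was not tested.

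Pseudocounts of 0.5 and 5, a minimum of 50 reads, no filter, TMM factors and edgeR kept every count of genes within 1.5 times, with these exceptions. The interaction at 12 h, 49 genes, was 91 with a pseudocount of 5 and 29 with no filter, and the interaction at 6 h, 861 genes, was 538 with no filter. Of the 310 named values past the threshold 223 stayed past it, in the same direction, under the alternatives chosen beforehand with all libraries. The minimum change of 1 log2 unit is left out of this number. With every single library left out 210 stayed, and under every setting, that minimum included, 185 stayed. A setting in which a gene was not tested was passed over for that gene.

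Quantile normalization gave 13 genes for IL-10 alone at 6 h, 387 for IL-10 alone at 12 h, and 418 and 82 for the interactions at 6 h and 12 h. It gave 89, 1208 and 9 for the differences between 12 h and 6 h in the IL-10 effect during LPS, in LPS and in IL-10 alone.

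A minimum change of 1 log2 unit lowers counts by its construction. At 3 h it left 3085 genes for LPS, 55 for IL-10 alone, 411 for IL-10 during LPS and 183 for the interaction. Genes shared between times fell to 134 higher and 87 lower for 3 h and 6 h, 50 and 10 for 3 h and 12 h, and 96 lower for 6 h and 12 h. Of genes that LPS had moved at 6 h, 68 of the induced were lowered and 54 of the lowered were raised at 3 h.

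A fit of only the groups compared uses fewer libraries to estimate the spread. It gave 13 genes for IL-10 alone at 3 h, 0 at 6 h and 0 at 12 h, 3286 for LPS at 12 h, 52 for IL-10 during LPS at 12 h and 1 for the interaction at 12 h. It gave 61 and 0 for the differences between times in the IL-10 effect during LPS and in IL-10 alone. IL-10 during LPS at 3 h went the other way, to 3301. With it shared genes were 459 higher and 490 lower (3 h and 6 h), 22 and 9 (3 h and 12 h) and 33 and 12 (6 h and 12 h). The carried lists gave 10 lowered and 3 raised at 12 h, and 501 and 216 at 3 h.

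The replicate block changed 4 of these counts, to 334 for IL-10 alone at 3 h, 30 for the interaction at 12 h, 85 for the IL-10 effect during LPS between times and 36 for LPS-lowered genes raised at 12 h. The replicate differences of 2 groups correlated between -0.05 and 0.27 at 3 h and between -0.41 and 0.70 in the second table, so the replicate numbers do not pair the libraries across all groups, although the control, LPS and LPS with IL-10 at 6 h shared differences (0.33 to 0.70).

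Without a trend limma called 67 genes for IL-10 alone at 3 h, 176 for the interaction at 3 h and 5 for IL-10 alone at 6 h, and 34 lower genes were shared by 3 h and 12 h. DESeq2, with 21.5% false calls for IL-10 during LPS at 12 h in the simulated data against 9.4% for limma, called 44 and 563 for IL-10 alone at 6 h and 12 h, and 1044 for IL-10 during LPS at 12 h. It called 1710 and 257 for the interactions at 6 h and 12 h, and 732 and 72 for the differences between times with and without LPS. Its shared lower genes were 80 for 3 h and 12 h and 229 for 6 h and 12 h, and the carried lists gave 117 lowered and 90 raised at 12 h.

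Equal library totals gave 32 genes for the interaction at 12 h. The carried lists are drawn anew under each setting, and here they gave 239 of 998 lowered and 1488 of 3353 raised at 6 h, 33 of 998 lowered at 12 h, and 119 of 1166 lowered and 217 of 6569 raised at 3 h, and shared lower genes were 35 (3 h and 12 h) and 68 (6 h and 12 h). By construction this setting lowers every gene of a library with more normalized reads, and it turned the change of Il10 with LPS at 6 h to -0.03. It called 16 lists by camera for LPS at 12 h instead of 10.

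Library weights gave 112, 1 and 53 genes for IL-10 alone at the 3 times, 2942 and 259 for IL-10 during LPS at 3 h and 12 h, 3758 for LPS at 12 h, 9 for the interaction at 12 h and 655 for IL-10 alone between times. Shared genes became 544 higher and 440 lower (3 h and 6 h) and 119 and 66 (6 h and 12 h), and the carried lists 22 lowered and 21 raised at 12 h and 402 and 280 at 3 h.

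Removing GC trends raised most counts, and it also removes trends that differ between groups. IL-10 alone came to 541, 23 and 871 genes, IL-10 during LPS to 2255, 4931 and 2001, and the interaction to 853, 2209 and 379. The differences between times came to 1078 (IL-10 effect during LPS), 4802 (LPS) and 25 (IL-10 alone). Shared genes were 544 higher and 500 lower (3 h and 6 h), 249 and 223 (3 h and 12 h) and 571 and 496 (6 h and 12 h), and the carried lists gave 181 lowered and 139 raised at 12 h, and 333 and 226 at 3 h.

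Without the first library of each 12 h group, which leaves 1 library in these groups, limma called 0 genes for IL-10 alone at 6 h, 32 at 12 h, 984 for IL-10 during LPS at 12 h, and 106 for the interaction at 12 h. It called 3, 230 and 0 for the differences between times in the IL-10 effect during LPS, in LPS and in IL-10 alone. Lower genes shared by 6 h and 12 h were 414.

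With single libraries left out, where the lone library of a group is assumed to vary like the other groups, counts ran from 45 to 1915 for IL-10 alone at 3 h, 0 to 9 at 6 h and 31 to 286 at 12 h. For IL-10 during LPS they ran from 473 to 2448 at 3 h, 866 to 4371 at 6 h and 86 to 991 at 12 h, and for the interaction from 103 to 1443, 148 to 4220 and 11 to 154. LPS at 12 h ran from 3794 to 6191. The differences between times ran from 9 to 903 (IL-10 effect during LPS), 495 to 3010 (LPS) and 0 to 60 (IL-10 alone). The highest counts at 3 h came without the second control, which leaves the shallowest control library. For IL-10 during LPS at 3 h the count was nearly as high without the first control.

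Camera at a preset correlation called 14, 13 and 10 lists for LPS at 3 h, 6 h and 12 h, 2, 8 and 11 for IL-10 alone and 4, 12 and 13 for IL-10 during LPS. With an estimated correlation it called 5, 0 and 0 for LPS, 0, 1 and 2 for IL-10 alone, and 0 at each time for IL-10 during LPS. Fry called 24, 21 and 20 for LPS, 1 for IL-10 alone at 6 h, and 9 and 5 for IL-10 during LPS at 3 h and 12 h. With single libraries left out camera called 2 to 6 and 5 to 10 lists for IL-10 alone at 3 h and 6 h, and 6 to 15 for IL-10 during LPS at 12 h. These counts hide changes of direction and losses, and every reversal of a called list in these comparisons is given here. For IL-10 alone at 6 h 5 of the 8 lists were kept, 2 lost and 1 reversed without the second control, and 4 kept and 4 lost without the first. For IL-10 alone at 12 h 8 were kept, 2 lost and 1 reversed without the second control, and for LPS at 12 h 8, 1 and 1 with quantile normalization. For IL-10 during LPS at 12 h 8 of 13 were kept without the first LPS library of 12 h and 7 without the second library of both, with 1 reversed each time, and 6 without the second LPS library. Without the first 12 h libraries 9 were kept, 3 lost and 1 reversed. Fry lost 9 of these 13 lists and 7 of the 8 for IL-10 alone at 6 h.

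The effect of depth on the counts was not tested. The shallowest library held 9337222 reads, where 1 read stands for 1.67 normalized reads, and Ifnb1, Il12a and Il23a had 3, 0 and 0 reads in the 3 h control.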

Other observations

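The settings named in the last paragraph were chosen after the values were seen, and the genes in the first paragraphs are list members with small p.

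Single genes with IL-10 during LPS can be followed over time. The Fc receptors Fcgr2b (1.23 ± 0.08), Fcgr3 (1.19 ± 0.08) and Fcgr4 (0.73 ± 0.12) rose at 3 h and Fcgr3 again at 6 h (1.04 ± 0.20) and 12 h (1.09 ± 0.20). The scavenger receptor Marco fell at 6 h (-2.57 ± 0.32) and 12 h (-1.62 ± 0.32). The matrix protease Mmp19 rose at 3 h (1.53 ± 0.12) and 6 h (3.25 ± 0.25) and the collagenase Mmp8 at 6 h (1.88 ± 0.29) and 12 h (1.51 ± 0.29). The urokinase receptor Plaur fell at 3 h (-1.43 ± 0.17) and 6 h (-2.92 ± 0.60). The cholesterol exporter Abca1 rose at 3 h (0.54 ± 0.09) and 6 h (1.84 ± 0.23), and its partner Abcg1 fell at 6 h (-1.50 ± 0.23). The desaturase Scd2, lowered by LPS at 6 h (-4.62 ± 0.33), rose with IL-10 at that time (3.70 ± 0.33).

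The transcription factor Cebpb rose with IL-10 during LPS at 3 h (1.94 ± 0.29) and 6 h (1.81 ± 0.22). Irf4, a factor of alternative activation, fell at 3 h (-1.79 ± 0.31) and 6 h (-2.90 ± 0.41). The repressor Nfil3 rose at 6 h (1.62 ± 0.18), and the AP-1 member Fosl2 rose at 3 h (2.26 ± 0.09), 6 h (1.92 ± 0.17) and 12 h (0.68 ± 0.17). The phosphatase Dusp4 fell at 3 h (-2.29 ± 0.16) and 6 h (-2.25 ± 0.28), opposite to Dusp1 at 3 h (2.04 ± 0.10).

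Correlation between replicates at 3 h was 0.982 in the control and 0.994 in each of the other groups. The control pair there holds the shallowest library, and the SD of its log2 difference was 0.53 against 0.31 to 0.33 in the other groups. Depth alone does not account for this. The chi-square per degree of freedom, which allows for counting error, was 27.9 in the control against 4.2 with LPS, 10.8 with IL-10 and 2.3 with both. With GC trends removed the number of genes changed by IL-10 during LPS at 12 h was 2001, against 630 with them.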
